A study of Mus musculus with 2 samples.

How the data were processed

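Whole kidneys of male wild-type B6 mice gave 2 single-nucleus libraries, 1 of the CACPR treatment and 1 of the Sham control, made with 10x Chromium 3-prime chemistry. Per the labels, nuclei were extracted by an outside provider aiming for 10000 nuclei per library. Whether a library held nuclei of a single mouse or of a pool is not given in the sources used here. The values analysed are raw UMI counts per gene and barcode as deposited, in matrices filtered to called barcodes and not normalised. Per the labels, the tools used were bcl2fastq, Cell Ranger 6.0.1 and 7.2.0 and Seurat 4.4.0, with genome build mm10. Which tool or version did which step, whether intronic reads were counted and on which strand is not given in the sources used here. Both matrices were checked to hold whole numbers for the same 32285 genes.

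All further steps were computed in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and igraph 0.11.9, and figures with matplotlib 3.10.9. Nuclei with at least 200 genes and under 5% mitochondrial UMIs were kept. The mitochondrial limit left out 3391 CACPR barcodes (35.6%) and 1753 Sham barcodes (17.8%), and the gene minimum left out none. Doublets were scored within each library against simulated doublets, 2 per nucleus, by their share among nearest neighbours, and the highest-scoring nuclei were removed at an expected rate of 0.8% per 1000 nuclei, 302 in the CACPR library and 528 in the Sham library. The kept nuclei, 5839 and 7594, summed 21213966 and 29488407 UMIs, with medians of 3040 and 3283 UMIs, 1607 and 1731.5 genes and 2.22 and 1.63% mitochondrial UMIs per nucleus. Malat1 made up 18.7% of kept UMIs in the CACPR library and 9.76% in the Sham library.

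Counts were scaled to 10000 per nucleus and logged, and 2000 variable genes seen in at least 10 nuclei, ranked within each library, were scaled with values limited to 10. Mitochondrial, ribosomal protein and a few ribosomal or nuclear RNA genes such as Malat1 were kept out of this ranking. The first 30 principal components of both libraries together, without batch correction, gave a graph of 20 nearest neighbours, with shared-neighbour weights under 0.05 dropped, which was clustered by the Leiden method at resolution 1 with seed 1. Clusters with at least 200 nuclei whose median UMI count was less than their library's median divided by 3 were split once more, a step chosen after seeing the data. The 33 resulting clusters were named from textbook marker genes: each cluster was compared with the other nuclei of the library holding most of it. A name needed at least 3 markers of at least 3 UMIs above 2-fold and a mean log2 marker ratio above 0.5 with a pseudocount of 10 CPM. Clusters of low UMI counts also needed a marker of their class among their top 10 genes. Clusters that failed stayed unnamed and outside every class. The names are therefore class-like assignments, and several classes are held by different clusters in the 2 libraries. Classes with at least 100 nuclei in each library were compared, 9 in all.

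UMIs were summed over the nuclei of a class in each library and divided by the class total. Log2 ratios of the CACPR over the Sham library carried a pseudocount of 5 CPM, while printed fold values are plain ratios with exact conditional intervals. CPM values have exact Poisson intervals and shares of nuclei exact binomial intervals, at 95%. Where a library had 0 UMIs the ratio is a lower bound against a floor of 3 counts. With 1 library per group no test was made. The counts set the precision: the proximal tubule sums of 9553344 and 13069499 UMIs give narrow intervals for all but the rarest genes, and the myeloid sums of 318738 and 473677 UMIs give wide ones. These intervals hold no variation between animals.

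Gene lists were written before the data were examined: 30 response lists with 533 distinct genes, of which 529 are in the matrices, and 7 check lists for RNA of other cells and RNA quality. A list gene was measured in a class when it reached 5 CPM in either library. For each list the number of genes at least 2-fold higher or lower and the median log2 ratio were computed. The percentile of the median among 10000 random lists matched on expression in 50 bins was computed too. It is printed only for some proximal tubule lists. Genes were named by a fixed rule. It took the largest ratios among genes with at least 50 CPM and 100 UMIs in the higher library and at least 25% of the level of their highest class in the same library, 12 in each direction in the proximal tubule and 5 elsewhere. Mitochondrial, ribosomal protein and haemoglobin genes, Xist, Tsix, a few Y-linked genes and gene models with Gm or Rik names were not eligible. The rule also took up to 4 genes of each list with at least 10 CPM. Shares of nuclei with a UMI were computed after thinning each nucleus to 1000 UMIs, leaving shallower nuclei out. A share of 0 is given with an upper limit of 3 nuclei over the number of nuclei, and endothelial-like nuclei served as the measure of free RNA. Gene identifiers were matched to GENCODE M21: all 408 named genes were found by identifier with the same symbol, 83 overlap a gene on the same strand and 160 a gene on the other strand, and UMIs of such genes and of close paralogs cannot be fully assigned.

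The method was tested on simulated data, with UMI sums of 3 classes drawn from Poisson distributions around the class's own profile at the depth of each library, and 50 genes altered at each of the ratios 0.25, 0.5, 2 and 4. The simulation holds counting error only and no clustering step. Every altered gene had the right direction in the proximal tubule and thick ascending limb, and 49 of 50 genes at ratio 0.5 in the myeloid class. The log2 ratio came within 0.5 of the true value for 100% of altered proximal tubule genes and at least 96% of thick ascending limb genes. In the myeloid class it did so for 68, 78, 94 and 92% at ratios 0.25, 0.5, 2 and 4, so sizes there are less exact. Unaltered genes passed 2-fold in 0 of 3702 cases in the proximal tubule, 0 of 3527 in the thick ascending limb and 30 of 4384 (0.684%) in the myeloid class. Intervals covered the true value for 96.1, 95.3 and 96% of genes. Of 200 unaltered lists per class, 6, 10 and 10 fell outside the central 95% of random lists.

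There were 14 alternatives chosen before the data were examined. They covered doublet removal, a filter of at least 500 genes and under 1% mitochondrial UMIs, Leiden resolutions 0.5 and 2, clustering each library on its own or without response genes, median-of-ratios scaling, nuclei weighted equally, and nuclei thinned to 1000 UMIs. The rest were a pseudocount of 1 CPM, subtraction of free RNA at 10% of the class's UMIs, no minimum for list genes, and unthinned or 500-UMI shares. Another 4 were added after seeing the data: no further split of low-UMI clusters, a limit of 20% mitochondrial UMIs, CPM without Malat1 and mitochondrial UMIs, and S1-S2-like proximal tubule nuclei alone. Podocyte and parietal epithelial nuclei were left out of the comparisons because they were too few.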

Results

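Nuclei from whole kidneys of male wild-type B6 mice were profiled by droplet single-nucleus RNA sequencing in 2 libraries, 1 from the CACPR treatment and 1 from a sham control for it. The labels do not spell out CACPR, which in kidney research commonly stands for cardiac arrest followed by cardiopulmonary resuscitation, a procedure that stops and then restores blood flow to the kidney. The time between the procedure and tissue collection is not given in the sources used here, and the age is listed as 18 without a unit. The CACPR library held 9532 barcodes and 29846036 UMIs (unique molecular identifiers, each standing for 1 captured RNA molecule), with a median of 2252 UMIs per barcode. The Sham library held 9875 barcodes and 38040477 UMIs, with a median of 3059. Mitochondrial transcripts made up a median of 3.54% of a barcode's UMIs in the CACPR library and 1.92% in the Sham library. After filtering, 5839 CACPR nuclei and 7594 Sham nuclei were compared. With 1 library per group there are no replicates and no test of the difference between groups was possible, so both values are given, and all intervals are 95% intervals that cover counting error only.

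The first question was which cell types the 2 libraries held. Both libraries held the main cell types of the kidney. Proximal tubule-like nuclei made up 27.0% of CACPR nuclei (25.9 to 28.1%) and 28.3% of Sham nuclei (27.3 to 29.4%). Endothelial-like nuclei made up 13.8% (12.96 to 14.8%) and 12.7% (11.9 to 13.4%). Thick ascending limb nuclei, which reabsorb salt in the loop of Henle, made up 10.5% of the CACPR library (9.77 to 11.4%) and 14.5% of the Sham library (13.7 to 15.3%). Stromal nuclei (fibroblasts, pericytes, smooth muscle and mesangial cells) made up 10.1% and 11.5%, distal convoluted and connecting tubule nuclei 8.34% and 10.0%, and principal cell nuclei of the collecting duct 4.88% and 4.36%. Intercalated cells accounted for 2.5004% and 3.24%, thin limbs for 2.43% and 2.66%, and myeloid cells for 2.77% and 2.21%. Podocytes (71 and 100 nuclei) and parietal epithelium (34 and 94 nuclei) were too few to compare. Clusters kept out of every class held 15.8% of CACPR nuclei and 7.89% of Sham nuclei. The proximal tubule share of the CACPR library depended on choices of processing: it was 42.8% with at least 500 genes and under 1% mitochondrial UMIs, and 42.6% when clusters of low UMI counts were not split further, a setting chosen after seeing the data. It was also 35.9% and 30.5% at Leiden resolutions 0.5 and 2 and 29.5% without response genes in the clustering. The Sham share was at most 29.1% in every setting tried, so the CACPR share was the higher one in these 5 settings and the lower one in the others. Nuclei yield, and the 35.6% of CACPR and 17.8% of Sham barcodes left out for their mitochondrial share, also set these shares.

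**Figure D1:**
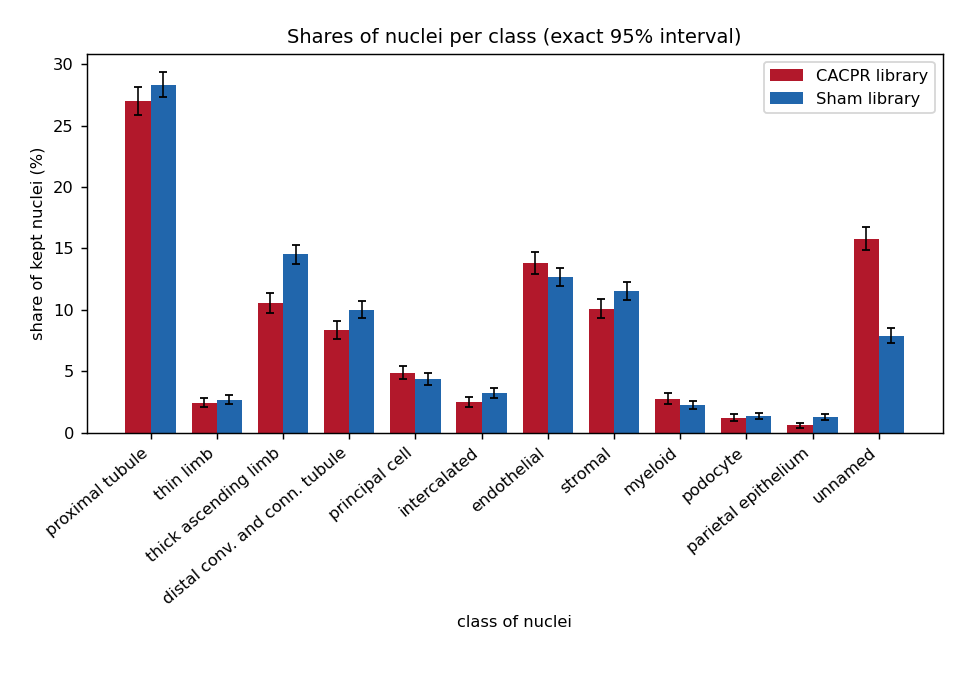
Share of kept nuclei (percent, vertical axis, starting at 0) in each class for the CACPR library (5839 nuclei) and the Sham library (7594 nuclei), with exact 95% binomial intervals as error bars. Proximal tubule shares are 27.0% and 28.3%, and unnamed clusters hold 15.8% and 7.89%.

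The main comparison asked how gene expression in the proximal tubule, the segment that reabsorbs most of the filtrate, differed between the CACPR and Sham libraries. Proximal tubule nuclei of the CACPR library carried high levels of the injury genes Havcr1 and Krt20, which were nearly absent from the Sham library, and less RNA of many transporters and of some enzymes of gluconeogenesis and NAD synthesis. Havcr1, which encodes kidney injury molecule 1, stood at 580 CPM (UMI counts scaled to the class total; 565 to 595) in the CACPR library and 0.689 CPM (0.315 to 1.31) in the Sham library, an 842-fold difference (443 to 1843). Of the 409 response-list genes measured here, 117 were at least 2-fold higher and 75 at least 2-fold lower in the CACPR library. The class summed 9553344 UMIs of 1576 CACPR nuclei and 13069499 UMIs of 2152 Sham nuclei, with median depths of 5670.5 and 5614.5 UMIs. Different clusters made up the class in the 2 libraries: clusters 0, 30 and 31 held its CACPR nuclei, and clusters 3, 5 and 11 nearly all of its Sham nuclei. Cluster 30 (128 CACPR nuclei) was led by stress genes, Hspa1a, Hspa1b, Fosb, Hmox1 and Atf3.

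Genes were ranked by the log2 ratio with a pseudocount of 5 CPM among those of at least 50 CPM and 100 UMIs that reached 25% of the level of their highest class. Among the others at the top of this ranking, Krt20, an intermediate filament keratin, reached 226 CPM (217 to 236) in the CACPR library against a single UMI (0.0765 CPM) in the Sham library, a ratio of 2956 with a counting interval from 530.0 to 116824. Fgg, the gamma chain of fibrinogen, was 144-fold higher (96.8 to 226; 265 and 1.84 CPM). Pdk4, a kinase that restrains pyruvate dehydrogenase, was 45.8-fold higher (41.3 to 50.8; 1317 and 28.8 CPM), and Plin2, a coat protein of lipid droplets, 37.8-fold higher (34.7 to 41.3; 1544 and 40.9 CPM). Hspa1a, an inducible chaperone with the near-identical paralog Hspa1b, was 109-fold higher (167 and 1.53 CPM), and Cxcl1, a neutrophil chemoattractant, 50.8-fold higher (256 and 5.05 CPM). Tnfrsf12a, the receptor of the cytokine TWEAK, stood at 150 and 3.75 CPM, and Cpe, a carboxypeptidase that processes prohormones, at 190 and 6.198 CPM. The stress cytokine Gdf15 (250.4 and 10.6 CPM), the antiproliferative gene Btg2 (164 and 5.43 CPM) and the zinc finger factor Klf6 (253 and 12.3 CPM) completed the 12 genes ranked highest towards the CACPR library. Towards the Sham library, Cyp7b1, an oxysterol hydroxylase, was 42.5-fold lower in the CACPR library (37.2 to 48.7; 23.3 and 991 CPM), and Slc22a28, of the organic anion transporter family, 41.1-fold lower (15.4 and 632 CPM). Its relative Slc22a30 (39.7 and 940.3 CPM), the acidic amino acid transporter Slc7a13 (25.3 and 658 CPM), the cytochrome Cyp2j11 (16.3 and 411 CPM), the carboxylesterase Ces1d (14.9 and 369 CPM) and the aminoadipate aminotransferase Aadat (43.65 and 813 CPM) were also lower. The remaining genes were Ctnna2, an alpha-catenin (5.97 and 310.2 CPM), BC024386 (7.33 and 302 CPM), the complement chain C8a (1.99 and 129 CPM), Nat8f6, an acetyltransferase family member (11.5 and 284 CPM), and Nxph1, a neurexophilin (1.15 and 97.2 CPM). In GENCODE M21 (build mm10), Havcr1 (ENSMUSG00000040405) lies on chromosome 11 from 46735080 to 46779578 on the plus strand, and Krt20 (ENSMUSG00000035775) on chromosome 11 from 99428403 to 99438150 on the minus strand. Pdk4 (ENSMUSG00000019577) lies on chromosome 6 from 5483351 to 5496309 on the minus strand, and Cyp7b1 (ENSMUSG00000039519) on chromosome 3 from 18071950 to 18243338 on the minus strand. Cyp7b1, Nat8f6 and Ctnna2 overlap other gene models, and Fgg and Hspa1a have a model on the opposite strand. Part of the UMIs of these genes may therefore belong to another gene. Cyp7b1, Slc7a13 and Aadat were also markers used to name S3 nuclei, and Cyp7b1 and C8a were among the top genes of Sham S3-like cluster 11. The proportion and naming of S3 nuclei in each library thus enter the ratios of these S3 genes.

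**Figure D2:**
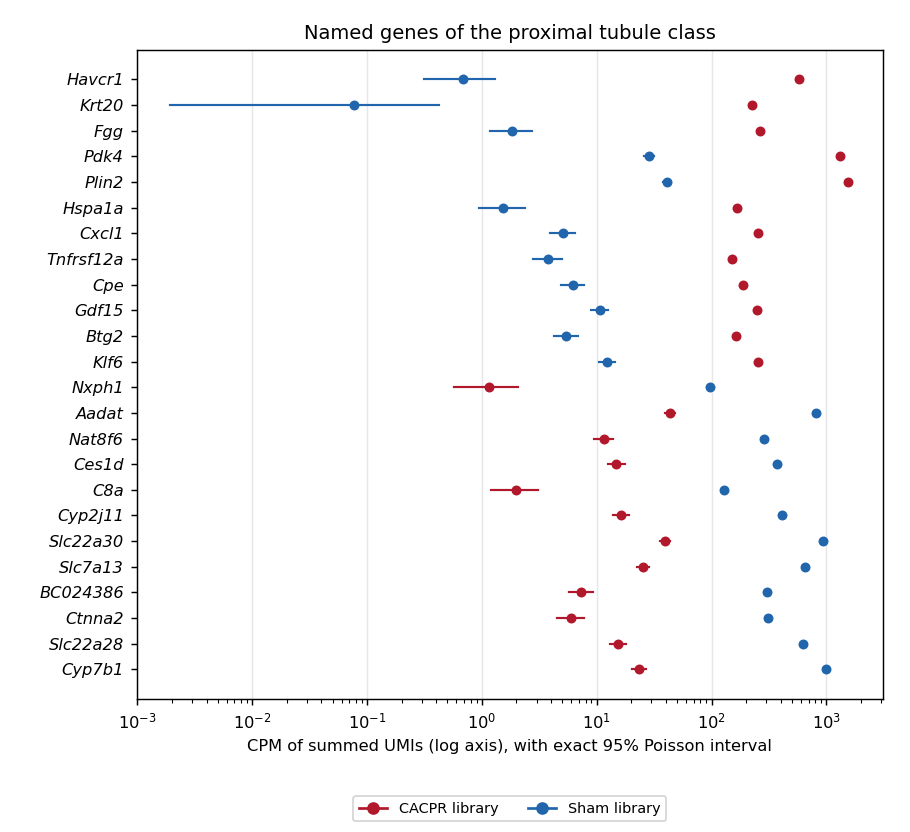
CPM of summed UMIs (log axis) for the 24 genes of the proximal tubule class, 12 in each direction, with the largest log2 ratios (pseudocount of 5 CPM) among genes past the minimum levels, with exact 95% Poisson intervals as horizontal bars. Havcr1 stands at 580 CPM in the CACPR library and 0.689 CPM in the Sham library, and Cyp7b1 at 23.3 and 991 CPM.

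Injury genes were higher and transport genes lower as groups. Of the 18 measured genes of the tubular injury list, 15 were at least 2-fold higher and none lower (median log2 ratio 2.35, above all 10000 random lists matched on expression). Spp1, which encodes osteopontin, stood at 1870.1 and 122.5 CPM. Lcn2, which encodes neutrophil gelatinase-associated lipocalin, stood at 198 and 0.765 CPM, 16.0% of its thick ascending limb level. Of 10 genes linked to failed repair, 6 were higher and none lower (median 1.26), with the cytokine Il34 at 418 and 43.8 CPM and the NF-kB subunit Relb at 26.5 and 1.38 CPM. Vcam1, another gene of that list, was near the bottom of the range in both libraries (6.07 and 3.06 CPM). Of 23 apical and basolateral transporters, 16 were lower and none higher (median -1.65, below all random lists). They included the phosphate transporter Slc34a1 (301 and 4357 CPM), the lactate transporter Slc5a12 (245 and 3057 CPM) and Slc16a9, a monocarboxylate transporter family member (32.9 and 474 CPM). The 10 albumin endocytosis genes split: the receptors Lrp2 (451 and 1479 CPM) and Cubn (189 and 438 CPM) were lower, and the lysosomal proteases Ctsl (378.5 and 143 CPM) and Ctsb (177 and 66.0 CPM) higher (median 0.21). Of 11 androgen-dependent proximal tubule genes, 8 were lower (median -1.63), with Cyp2j13 at 59.9 and 797.5 CPM. S3-like nuclei, which carry much of the androgen-dependent program, made up 4.01% of CACPR nuclei and 6.97% of Sham nuclei. The CACPR S3-like nuclei were all in clusters 30 and 31, which exist only through the further split chosen after seeing the data.

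Metabolic gene groups pointed in different directions. Of 10 gluconeogenesis genes, 5 were lower and 2 higher (median -1.20, percentile 0.46 among random lists): G6pc, the catalytic subunit of glucose 6-phosphatase, stood at 109 and 998 CPM. Its partner transporter Slc37a4 stood at 16.3 and 148.5 CPM and Fbp1 at 117 and 447 CPM. The aminotransferase Gpt2 was higher (65.2 and 12.2 CPM). Of 11 genes of NAD synthesis and salvage, 7 were lower and none higher (median -1.27). Among them were the kynurenine pathway genes Haao (11.2 and 114 CPM), Afmid (23.9 and 131 CPM) and Kynu (14.9 and 60.8 CPM). Acmsd (5.76 and 153 CPM), also in the list, was lower too, but its enzyme draws an intermediate of that pathway away from NAD. The list of fatty acid oxidation and PPARA targets split, with 8 of 29 genes higher and 5 lower (median 0.34, percentile 98.9 among random lists). Pdk4 and the peroxisomal enzyme Ehhadh (799 and 118 CPM) were higher, and the acyl-CoA synthetase Acsm2 (201 and 3044 CPM) and the peroxisomal oxidase Acox3 (45.95 and 306 CPM) lower. The fatty acid hydroxylase Cyp4a14 (133 and 26.6 CPM), chosen after its values were seen, was also higher. Of 15 glycolysis genes, 3 were higher and none lower (median 0.44), with Gapdh at 222.5 and 98.7 CPM. Of 27 nuclear genes of the respiratory chain, none passed 2-fold (median 0.02). Cholesterol synthesis genes had a median of -0.49, with Hmgcs1 lower (57.3 and 301 CPM) among 4 of 17.

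Stress and inflammatory lists differed in how many genes were higher. Of 19 immediate early and AP-1 genes, 17 were higher and none lower (median 2.21). Fosl1 stood at 60.9 CPM against a single Sham UMI (ratio 796, counting interval 142 to 31502). Atf3 stood at 33.5 CPM against no Sham UMI, at least 146-fold higher against a floor of 3 counts in the class. Among S1-S2-like nuclei alone, a setting chosen after seeing the data, 11 of 17 immediate early genes were higher. NRF2 targets, which answer oxidative stress, were higher in 12 of 16 cases (median 1.65). They included the haem oxygenase Hmox1 (125 and 3.83 CPM), the sulfiredoxin Srxn1 (134 and 7.12 CPM) and the cystine transporter Slc7a11 (23.8 and 0.383 CPM). Heat shock genes were higher in 11 of 15 cases (median 1.27), with Hspb1 at 85.2 and 2.07 CPM and Hsp90aa1 at 369.8 and 54.8 CPM. Of 13 genes of the acute phase and IL-6 family list, 9 were higher (median 2.09). Among them were the fibrinogen chains Fgg, Fgb (68.7 and 0.306 CPM) and Fga (164 and 13.2 CPM). Of 14 NF-kB and chemokine genes, 8 were higher (median 1.08), among them Cxcl1 and Cxcl2 (38.3 CPM against no Sham UMI, at least 167-fold higher). Among p53 targets 4 of 14 were higher (median 0.85), including the cell cycle inhibitor Cdkn1a (72.5 and 2.68 CPM) and Gdf15. Genes of the unfolded protein and integrated stress response were higher in 6 and lower in 2 of 14 cases (median 0.40), with Atf4 at 101 and 27.8 CPM and Herpud1 at 99.5 and 255 CPM. Ferroptosis and iron genes were higher in 4 and lower in 1 of 13 cases (median 0.72), among them Hmox1, Slc7a11 and the lipid-activating enzyme Acsl4 (340.3 and 31.8 CPM). Of 13 matrix and myofibroblast genes, 6 were higher (median 0.97), among them the matricellular protein gene Ccn1 (154 and 6.66 CPM). Ribosomal protein genes had a median log2 ratio of 0.85 and mitochondrially encoded genes of 0.31 in the same class, and the nuclear RNA Malat1 stood at 196152 and 87669 CPM.

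Other groups differed less or went both ways. Hypoxia genes were higher in 3 and lower in 4 of 19 cases (median 0.24). The glucose transporter Slc2a1 was higher (58.0 and 5.66 CPM) and the oxygen sensor Egln3 lower (3.77 and 17.4 CPM). Glucocorticoid response genes were higher in 5 and lower in 4 of 15 cases (median 0.61). The metallothioneins Mt1 (774 and 42.3 CPM) and Mt2 (243 and 8.34 CPM) in that list stood at under 25% of their stromal level. Circadian clock genes were lower in 7 and higher in 4 of 18 cases (median -0.29). The clock output factors Tef (55.9 and 557 CPM) and Hlf (31.4 and 231 CPM) and the protease Usp2 (13.6 and 185 CPM) were lower and Npas2 higher (66.6 and 9.64 CPM). Cell cycle genes gave 1 higher and 1 lower of 9 measured (median 0.54), Pcna (16.7 and 4.59 CPM) and Kif20b (12.04 and 80.8 CPM). Kif20b marked Sham S3-like cluster 11, and its log2 ratio was 0.23 in S1-S2-like nuclei alone. Of 7 interferon response genes measured, 1 was higher (median 0.20), and of 10 slit diaphragm and cytoskeleton genes 3 were higher and 1 lower (median 0.18).

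Havcr1 RNA was spread over many proximal tubule nuclei. After each nucleus was thinned to 1000 UMIs, 28.2% of CACPR proximal tubule nuclei (26.0 to 30.5%; 436 of 1547, 29 shallower nuclei left out, median depth 5733 UMIs before thinning) had a Havcr1 UMI. In the Sham library 0.0467% had one (1 of 2143, 9 left out, median depth 5631). Endothelial nuclei, which should lack the gene and show the level of free RNA, had 4.65% (3.22 to 6.47%; 710 nuclei, 98 left out, median depth 2037) and 0 of 899 (63 left out, median depth 2024), which allows a share of up to 0.334%. Without thinning the proximal tubule shares were 52.7% and 0.372%, and the endothelial shares 8.04% and 0 of 962. Krt20 was found in 14.5% of thinned CACPR proximal tubule nuclei and in none of the Sham nuclei (limit 0.140%; 39.8% and 0.0465% unthinned), against 6.34% of CACPR endothelial nuclei (11.1% unthinned). Lcn2 was most widespread in the thick ascending limb, with 65.6% of 610 thinned CACPR nuclei (6 left out, median depth 3413) and 0.184% of 1089 Sham nuclei (13 left out, median depth 3235; 92.5% and 0.726% unthinned). It was found in 42.3% and 0.445% of endothelial nuclei (68.7% and 0.728% unthinned) and in 19.4% and 0.0467% of proximal tubule nuclei (67.6% and 0.465% unthinned). Spp1 was found in 77.6% and 11.99% of proximal tubule nuclei (100% and 47.5% unthinned) and 93.8% and 26.0% of endothelial nuclei (99.8% and 43.2% unthinned). Cdkn1a was found in 7.05% of proximal tubule nuclei in the CACPR library and 0.233% in the Sham library (30.5% and 1.63% unthinned) against 18.7% and 6.12% of endothelial nuclei (32.4% and 11.7% unthinned). The proximal tubule share of Spp1 did not stand above the endothelial one. Vcam1 was found in 0.711% and 0.327% of proximal tubule nuclei (3.62% and 1.86% unthinned) and in 11.97% and 4.89% of endothelial nuclei (16.5% and 7.59% unthinned). Endothelial nuclei express Cdkn1a and Vcam1 themselves, so their shares give no level of free RNA for these genes. Fos was found in 1.10% and 0.140% (3.62% and 0.325% unthinned) against 0.986% and 0.111% (1.73% and 0.520% unthinned). The proliferation genes Mki67 (0.388% and 0.513%; 1.33% and 1.81% unthinned) and Top2a (0.0646% and 0.140%; 0.508% and 0.279% unthinned) were rare in the proximal tubule of both libraries. Of endothelial nuclei, 0.282% and 0.445% had a Mki67 UMI (0.248% and 0.624% unthinned) and 0.282% and 0.556% a Top2a UMI (0.371% and 0.520% unthinned).

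**Figure D3:**
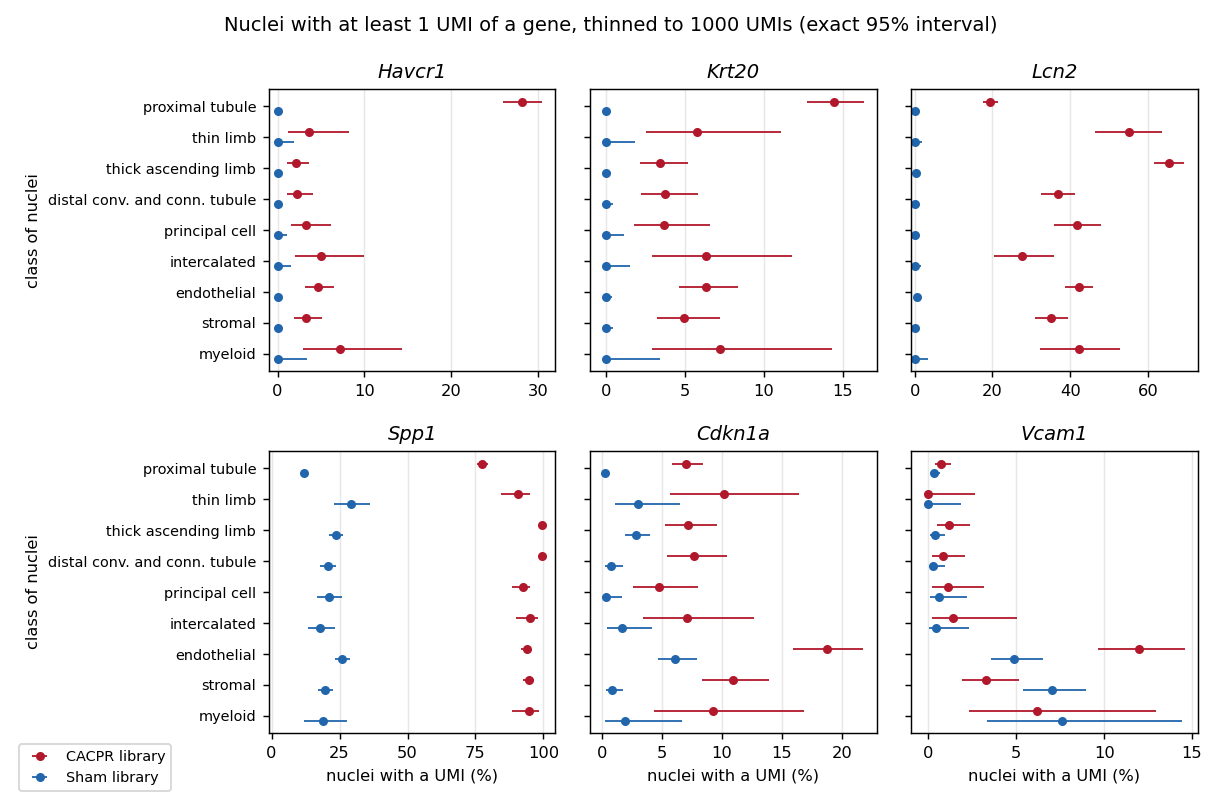
Share of nuclei (percent, horizontal axes) with at least 1 UMI of Havcr1, Krt20, Lcn2, Spp1, Cdkn1a or Vcam1 in each of the 9 compared classes after thinning to 1000 UMIs, with exact 95% binomial intervals. Havcr1 reaches 28.2% of CACPR proximal tubule nuclei against 4.65% of CACPR endothelial nuclei, and Lcn2 reaches 65.6% of CACPR thick ascending limb nuclei.

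In the thick ascending limb, the distal convoluted and connecting tubule and the principal cells, the secreted injury protein gene Lcn2 was higher and transport genes were lower in the CACPR library. In the thick ascending limb (616 CACPR nuclei, nearly all in cluster 7, and 1102 Sham nuclei, nearly all in clusters 8 and 10), Lcn2 was 513-fold higher (269.9 to 1123; 1236 and 2.41 CPM) and Spp1 28.8-fold higher (7394 and 257 CPM). Egf, a growth factor made in this segment, was 82.3-fold lower (72.6 to 93.7; 109 and 9007 CPM), and Slc12a1, the salt cotransporter of the loop, 31.2-fold lower (29.5 to 33.1; 547 and 17081 CPM). The cytokine signalling inhibitor Socs3 (131 and 1.61 CPM) and the protease Adamts1 (172 and 5.62 CPM) were also higher, and Abca13 (63.9 and 2792 CPM), Tmem207 (8.93 and 279.5 CPM) and Cabcoco1 (7.15 and 226 CPM) lower. Of the 21 thick ascending limb transport genes, 17 were lower and none higher (median -1.85), with the metabolic regulators Ppargc1a (198 and 2255 CPM) and Esrrb (88.9 and 971 CPM) among them. The median of all expressed genes was shifted by -0.14 in this class, and relative to it the transport list stood at -1.71.

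In the distal convoluted and connecting tubule (487 CACPR nuclei, nearly all in cluster 13, and 761 Sham nuclei, nearly all in clusters 14 and 15), Lcn2 stood at 439 CPM against 2 Sham UMIs (ratio 705, counting interval 195 to 5829), and Spp1 at 6668 and 220 CPM. Gdf15 (103 and 1.56 CPM) and the metallothioneins Mt1 (1738 and 125 CPM) and Mt2 (544 and 29.6 CPM) were higher. Of 24 distal and collecting duct transport genes, 14 were lower and none higher (median -1.03). They included the kinase Wnk1 (519.7 and 6088 CPM), its regulator Klhl3 (108 and 1972 CPM), the calcium exchanger Slc8a1 (2627 and 35099 CPM) and Slc12a3, the thiazide-sensitive cotransporter (2122 and 12591 CPM). Cluster 13 was named connecting tubule-like by its markers but was led by the distal convoluted genes Slc12a3 and Trpm6 and also held the connecting tubule gene Calb1, while the Sham nuclei formed a distal convoluted cluster (389 nuclei) and a connecting tubule cluster. The proportion of the segments in the CACPR class is therefore not known and enters these ratios. Egf (82.2 and 3071 CPM), Abca13 (337 and 7266 CPM) and Esrrb (40.3 and 567.5 CPM) were lower. Principal cells (285 nuclei in cluster 16 against 331, mostly in cluster 19) had higher Lcn2 (525 and 3.62 CPM), Sprr2f (122 CPM against no Sham UMI, at least 44.9-fold), the hexokinase Hk2 (180.3 and 3.62 CPM) and Gdf15 (215 and 9.06 CPM). Rhcg, an ammonia channel (26.1 and 586 CPM), Wscd2 (4.17 and 145 CPM), Klhl14 (14.6 and 286 CPM), AI838599 (12.5 and 240.0 CPM) and Apela, a peptide hormone (40.7 and 612 CPM), were lower there. In the same class 13 of 23 distal transport genes were lower and 1 higher (median -1.09). Cluster 16, led by the urea transporter gene Slc14a2, held 66 of the Sham nuclei, and cluster 19 held 265 Sham and no CACPR nuclei. Whether both libraries held the same parts of the collecting duct is therefore not known, and this enters the ratios. Intercalated cells (146 and 246 nuclei) had higher Spp1 (4407 and 229 CPM), Lrrc36 (213 and 9.45 CPM), Cebpd (182 and 21.7 CPM), Vmp1 (687 and 133 CPM) and Klf6 (199 and 37.8 CPM). Their anion exchangers Slc4a1 (1 CACPR UMI against 108 CPM, ratio 63.4, counting interval 11.2 to 2525) and Slc26a7 (3 CACPR UMIs against 136 CPM, ratio 26.7, counting interval 8.95 to 131) were lower, as were Tmem117 (755 and 9880.2 CPM), Ror1 (11.9 and 211 CPM) and Slc16a7 (66.3 and 891 CPM). Thin limb nuclei (142 and 202) had higher Lcn2 (730.3 CPM against 2 Sham UMIs, ratio 198, counting interval 54.5 to 1645), Sh2d4b (303 and 7.36 CPM), Mt2 (543 and 22.1 CPM), Plin2 (403 and 23.9 CPM) and Runx1 (355 and 23.9 CPM). They had lower Corin (15.3 and 613 CPM), Apela (32.7 and 821 CPM), Galnt14 (48.0 and 762 CPM), Klhl14 (15.3 and 252 CPM) and Uncx (10.9 and 186 CPM).

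Endothelial, stromal and myeloid nuclei shared higher Lcn2 and Spp1 and lower interferon response genes in the CACPR library. Endothelial nuclei (808, mostly in cluster 4, against 962, mostly in cluster 2) had 186-fold higher Lcn2 (89.8 to 463; 623 and 3.36 CPM) and higher Mt1 (1759 and 102 CPM) and Mt2 (723 and 28.8 CPM). Also higher were Cyp26b1, a retinoic acid hydroxylase (264 and 7.67 CPM), and Inhbb, an activin subunit (240.3 and 10.1 CPM). Ctnna3 (22.1 and 201 CPM), the interferon-inducible Ifi203 (39.4 and 321 CPM), Samd12 (146 and 1070.2 CPM), the peptide transporter Slc15a2 (8.37 and 82.5 CPM) and the muscarinic receptor Chrm3 (193 and 1234 CPM) were lower. Of 22 endothelial activation and barrier genes, 7 were higher and 1 lower (median 0.66). Among them were the leukocyte adhesion receptors Selp (37.1 CPM against 1 Sham UMI, ratio 77.2, counting interval 13.4 to 3100) and Sele (38.2 CPM against 3 Sham UMIs, ratio 26.6, counting interval 8.70 to 132), the peptide Apln (62.2 and 1.92 CPM) and the anticoagulant receptor Thbd (267 and 63.8 CPM). Of 22 interferon response genes, 13 were lower and none higher (median -1.15), including Ifi44 (65.1 and 246 CPM) and Usp18 (11.95 and 51.8 CPM). With at least 500 genes and under 1% mitochondrial UMIs, 3 of 20 interferon genes were lower and the activation median was -0.15. That class held 133 CACPR and 285 Sham nuclei, of which 23 and 83 were endothelial in the main setting. Another 62 and 169 had been removed as doublets there and so had no class.

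Stromal nuclei (589, mostly in cluster 12, against 877, mostly in cluster 6) had higher Lcn2 (442 and 1.57 CPM), Tnc, a matrix protein of wound repair (1286 and 23.5 CPM), Plin2 (443 and 17.2 CPM), Spp1 (3376 and 196 CPM) and Tnfrsf12a (159 and 5.48 CPM). Of 21 matrix and myofibroblast genes, 9 were higher and 1 lower (median 0.60), among them the protease inhibitor Timp1 (104 and 3.13 CPM), Tgfb1 (102 and 25.4 CPM) and its receptor Tgfbr1 (489 and 128 CPM). Matn2 (31.1 and 339 CPM), Abca9 (16.8 and 198 CPM), Acss3 (15.5 and 247 CPM), Armc2 (1 CACPR UMI against 65.0 CPM, ratio 100.3, counting interval 17.8 to 3984) and Lrfn2 (3 CACPR UMIs against 56.3 CPM, ratio 29.0, counting interval 9.73 to 142) were lower. Interferon response genes were lower in 10 of 21 cases (median -0.92), with Oasl2 at 25.3 and 79.0 CPM. Myeloid nuclei (162 and 168, both in cluster 18) had Lcn2 at 684 CPM against no Sham UMI (at least 108-fold higher). Rgs1, a regulator of chemokine signalling, stood at 458 CPM against 2 Sham UMIs (ratio 108, counting interval 29.5 to 904). Spp1 (4094 and 217 CPM), Mt2 (587 and 29.6 CPM) and Plin2 (831 and 52.8 CPM) were also higher. Of 18 macrophage activation genes, 8 were higher and 5 lower (median 0.65). Of all 490 response-list genes measured in this class, 127 were at least 2-fold higher and 109 at least 2-fold lower. The chitinase-like gene Chil3 was higher (65.9 CPM against 2 Sham UMIs, ratio 15.6, counting interval 3.81 to 137). The resident macrophage gene Cd163 (3 CACPR UMIs against 131 CPM, ratio 13.9, counting interval 4.54 to 69.3) and F13a1 (65.9 and 574 CPM) were lower. Interferon genes were lower in 12 of 21 cases (median -1.12). The myeloid genes ranked highest towards the Sham library were proximal tubule genes, Slc5a12 (15.7 and 851 CPM), Aspa (1 CACPR UMI against 217 CPM, ratio 69.3, counting interval 12.2 to 2764), Pbld1 (2 CACPR UMIs against 217 CPM, ratio 34.7, counting interval 9.35 to 290), Cyp2j13 (3 CACPR UMIs against 277 CPM, ratio 29.4, counting interval 9.84 to 144) and G6pc (22.0 and 372 CPM), at 27.8 to 37.2% of their proximal tubule level in the Sham library. The macrophage count was 4 of 17 and the median -0.05 with nuclei under 20% mitochondrial UMIs, a setting chosen after seeing the data, and 5 of 20 with nuclei weighted equally.

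**Figure D4:**
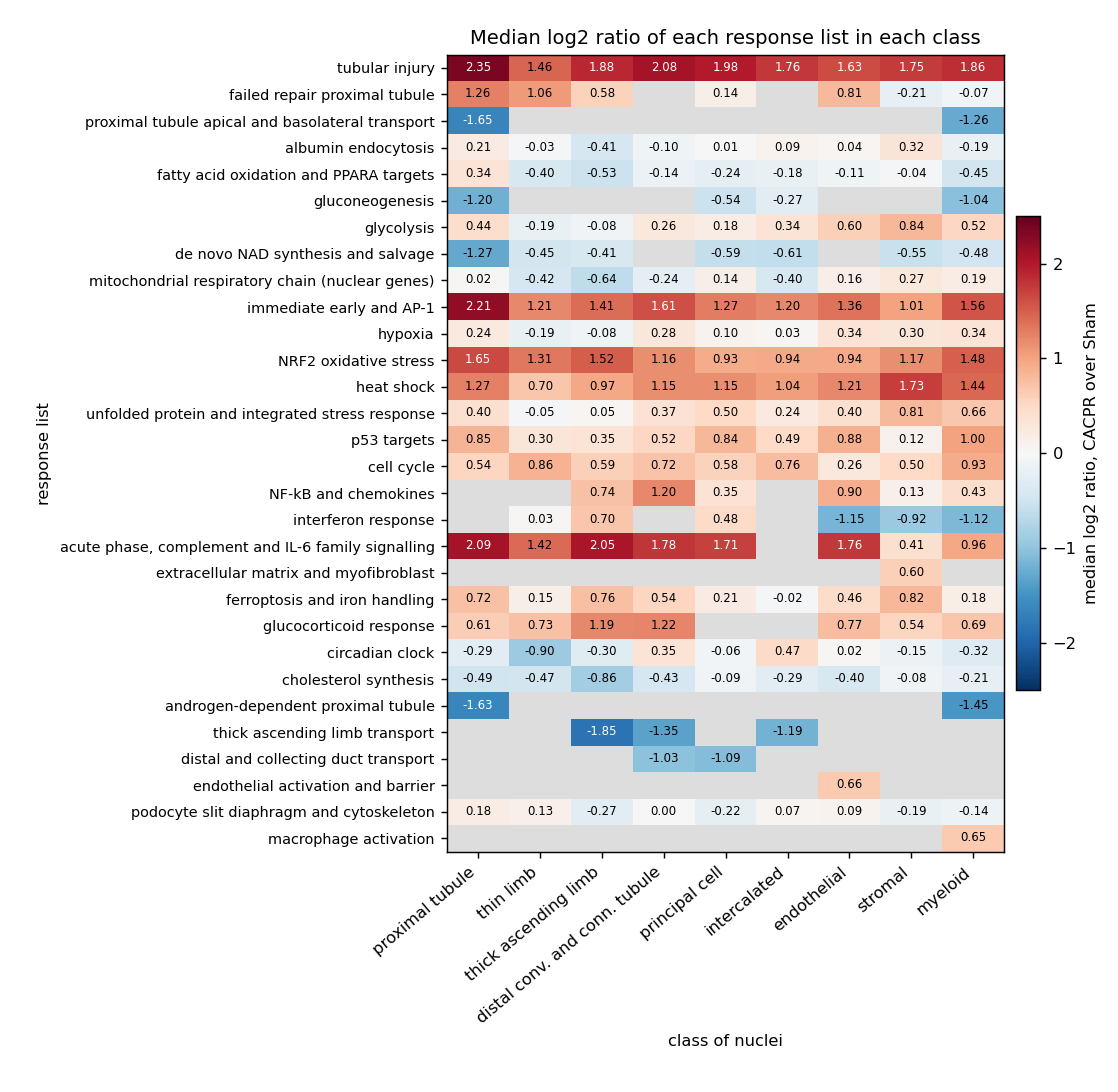
Median log2 ratio (CACPR over Sham, pseudocount of 5 CPM) of each response list in each of the 9 compared classes. Grey fields have under 3 measured genes or, except for tubular injury, too few genes at their own level in the class, tubular injury medians run from 1.46 to 2.35 and immediate early medians from 1.01 to 2.21, and interferon medians are -1.15, -0.92 and -1.12 in endothelial, stromal and myeloid nuclei.

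The tubular injury, immediate early, NRF2 and heat shock lists had positive medians in all 9 compared classes, from 1.46 to 2.35, 1.01 to 2.21, 0.93 to 1.65 and 0.70 to 1.73. Setting genes without UMIs in a library to the bound of their counts left every proximal tubule median as it was, and moved those of tubular injury in endothelial (1.73), intercalated (1.77) and thin limb nuclei (1.34) and of immediate early genes in thin limb (0.99) and myeloid nuclei (1.503). In the same classes the ribosomal protein genes had medians from 0.42 to 1.44. Lcn2 was at least 2-fold higher in all 9 classes (log2 ratio 5.14 to 7.39), as was Spp1 (2.93 to 4.89), and Cdkn1a, Gdf15, Hmox1, Mt1, Mt2 and Pdk4 were also among the 36 response genes at least 2-fold higher in every class. Havcr1 (2.25 to 6.68) and Krt20 (2.94 to 5.51) were among these 36 genes too, and 17 response genes were at least 2-fold lower in every class, among them the tubule genes Slc12a1, Egf, Slc5a12 and Lrp2. With free RNA subtracted at 10% of the class's UMIs, Havcr1 stood at -0.18 in the distal convoluted and connecting tubule and was less than 2-fold higher in thick ascending limb, principal cell and intercalated nuclei. Genes of this paragraph were chosen after their values were seen. Free RNA of the tubule thus enters the ratios of every class, and the tubular injury medians outside the tubule do not show a response of those cells.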

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

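The tests of free RNA for Lcn2, depth, segment mix, segment shares, the share of UMIs left for other genes and cytoplasmic RNA below were written after the results were seen, and the others, including that of free RNA for Mt1, before. With 1 library per group they cannot separate treatment from differences between mice or preparations.

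Lcn2 and the metallothioneins were higher in every compared class of the CACPR library, which free RNA from injured tubules could produce. If a single pool of free RNA supplied these genes and Spp1 alike, each would stand in the same proportion to Spp1 in each non-tubular class. The proportion of Lcn2 in endothelial nuclei was 1.40 times that in stromal nuclei (1.26 to 1.55). That of Mt1 in stromal nuclei was 3.01 times that in myeloid nuclei (2.71 to 3.34). A single pool for all of them would not give these values. Spp1 or Mt1 made by the cells themselves would shift the proportions even if all Lcn2 were free RNA. The values therefore do not decide the source of Lcn2. Depth does not account for the higher Lcn2, since 42.3% of CACPR and 0.445% of Sham endothelial nuclei had a Lcn2 UMI at equal depth. Free RNA of single or mixed origin could still supply part or all of the Lcn2 signal and part of the metallothionein signal.

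Some PPARA target genes, Pdk4 among them, were higher in the proximal tubule of the CACPR library, 8 of 29 in the fatty acid oxidation list against 5 lower. A segment's share of the UMIs of the class was at most 1.15-fold higher in the CACPR library. As far as the segment names hold, a different mix of S1-S2-like and S3-like nuclei thus cannot carry a gene past 2-fold. These names rest on the further split chosen after seeing the data, from which all CACPR S3-like nuclei (clusters 30 and 31) came. S1 and S2 share a name, and nearly all Sham nuclei of that name formed clusters 3 and 5 (821 and 797 nuclei) against cluster 0 in the CACPR library. A different mix of S1 and S2 is therefore not excluded. The UMIs left for other genes beside Malat1 and mitochondrial genes were 0.875 times the Sham share, which lowers these genes in the CACPR library. The 8 genes had median log2 ratios of 1.82 in S1-S2-like nuclei, 0.59 in S3-like nuclei and 1.98 without Malat1 and mitochondrial UMIs, values that decide nothing here because of how the genes were chosen and the scale set. Nuclear-encoded respiratory chain genes had a median of 0.024, while ribosomal protein and mitochondrially encoded genes had positive medians in the same class. These lists disagree, so they do not decide whether the CACPR nuclei carried more cytoplasmic RNA. A fasting-like or stress hormone state stays open too. Of 15 glucocorticoid response genes 5 were higher and 4 lower, and of 10 gluconeogenesis genes 5 were lower and 2 higher (median -1.20).

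Interferon response genes were lower in endothelial, stromal and myeloid nuclei of the CACPR library. Dilution by RNA of other cells would also lower the class's own markers, which had median log2 ratios of -0.16, -0.12 and 0.11 in the 3 classes. In endothelial nuclei under 2% mitochondrial UMIs the interferon median was -1.01, with 12 of 22 genes lower in 247 CACPR and 486 Sham nuclei. With at least 500 genes and under 1% mitochondrial UMIs 3 of 20 genes were lower. Of the 133 CACPR and 285 Sham nuclei then in the class, 23 and 83 were endothelial in the main setting. Another 62 and 169 had been removed as doublets there and so had no class. This value rests on largely different nuclei, and whether the interferon pattern holds under that filter stays open. A higher interferon tone in the Sham library's tissue could give the pattern as well.

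Some groups pointed in opposite directions between classes, and differences between classes were not tested. Fatty acid oxidation genes had a median log2 ratio of 0.34 in the proximal tubule and -0.53 in the thick ascending limb. The interferon list had 0.70 in the thick ascending limb, where 9 genes were measured, and -1.15 in endothelial nuclei. Circadian clock genes had 0.47 in intercalated and -0.90 in thin limb nuclei. Some data stayed outside the classes: unnamed cluster 28 held 3.68% of CACPR nuclei and none of the Sham nuclei, and unnamed cluster 29 held 2.45% of CACPR and 0.0658% of Sham nuclei. CACPR barcodes left out for their mitochondrial share carried Havcr1 at 131 CPM (827 UMIs), against none in the Sham barcodes left out.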

How the results depend on the processing

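No paired analysis was possible because each group has 1 library. Across all settings 6987 of 7576 list counts, 2789 of 3009 list medians and 12712 of 13420 named gene ratios stayed within the set tolerance, as did 109 of 158 class shares and 320 of 486 UMI shares, and 2 medians and 7 gene ratios turned direction. Part of these totals was fixed in advance. Dropping the minimum for list genes cannot change a named gene ratio or a 2-fold list count. Median-of-ratios scaling shifted each class by less than the tolerance, so it could not move a median or a named gene ratio. The cause was not tested for any value below. With at least 500 genes and under 1% mitochondrial UMIs only proximal tubule, distal convoluted and connecting tubule, and endothelial nuclei were enough to compare, so the other classes gave no value. The proximal tubule share of CACPR nuclei was 25.6% without doublet removal, 42.8% with the 500-gene filter, 35.9% and 30.5% at Leiden resolutions 0.5 and 2, 18.9% with each library clustered on its own, 29.5% without response genes in the clustering, and 42.6% without the further split. The Sham share was at most 29.1%, so the CACPR share was below it in some settings and above it in others. It was 26.4% without doublet removal and 20.5% with separate clustering. With the 500-gene filter, 3 of 20 interferon genes were lower in the class named endothelial, the activation median was -0.15, and 109 of 472 response genes were lower. In that class 23 of 133 CACPR nuclei and 83 of 285 Sham nuclei were endothelial in the main setting. Another 62 and 169 had been removed as doublets there and so had no class. These values therefore rest on a largely different set of nuclei. Macrophage genes higher in myeloid nuclei numbered 4 of 17 (median -0.046) under 20% mitochondrial UMIs and 5 of 20 with nuclei weighted equally. Thinned to 1000 UMIs, log2 ratios were 0.40 for Cxcl10 in intercalated, -0.052 for Atf4 in myeloid, -0.013 for Aen in principal cell, and -0.25 for Fcgrt and -0.30 for Mcm6 in thin limb nuclei. With free RNA subtracted Havcr1 stood at -0.18 in the distal convoluted and connecting tubule. In S1-S2-like nuclei alone 11 of 17 immediate early genes were higher and Kif20b stood at 0.23. Proximal tubule nuclei with a Havcr1 UMI made up 52.7% and 0.372% unthinned, and 17.6% of CACPR nuclei thinned to 500 UMIs. The missing further split, the 20% limit, CPM without Malat1 and mitochondrial UMIs, and S1-S2-like nuclei alone were added after seeing the data.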

Other observations

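Clock genes differed in the same direction in most cell types, as a difference in the hour of collection between the 2 libraries would also do. Cry1 and Bhlhe40 were at least 2-fold higher in all 9 compared classes of the CACPR library, with median log2 ratios of 1.496 and 2.14. The output factors Tef and Hlf and the protease Usp2 were lower by any amount in all 9 classes, with medians of -1.36, -1.29 and -1.98. They were at least 2-fold lower in 6, 6 and 7 of these classes. Npas2 was at least 2-fold higher in 7 classes and lower in 2. The hour of collection is not given in the sources used here.

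Most nuclei outside the named classes were in clusters of low UMI counts. Among these, haemoglobin genes led cluster 1, with 552 CACPR nuclei (9.45%) and 12 Sham nuclei, and cluster 9, with 6 CACPR nuclei and 325 Sham nuclei (4.28%). Cluster 32 held 5 CACPR nuclei and 211 Sham nuclei. Cluster 28, with 215 CACPR nuclei, had Krt20 at 715 CPM and the autophagy receptor Sqstm1 at 1029 CPM, against 166 and 298 CPM in the whole CACPR library. Its Spp1 (2263 against 3542 CPM) and Lcn2 (284 against 453 CPM) were below the level of the whole library, and its Havcr1 (279.8 against 306 CPM) differed from it by less than counting error. Cluster 29, with 143 CACPR nuclei, had Havcr1 at 773 CPM, the chemokine Cxcl2 at 164 CPM and Mlkl, an effector of necroptosis, at 103 CPM, and its Spp1 (3047 CPM) was below the level of the whole library. The injured proximal tubule markers were at 27.7 CPM in cluster 28 and 50.05 CPM in cluster 29 against 66.6 CPM in the whole library. Other proximal tubule genes went both ways in clusters 28 and 29. Slc34a1 stood at 392 and 551 CPM against 265 CPM in the whole library, and Lrp2 at 191 and 209 CPM against 244 CPM. The S1-S2 markers were at 41.9 and 79.2 CPM against 84.0 CPM. Cluster 1, led by haemoglobin genes, had Slc34a1 at 883 CPM, so a raised Slc34a1 level alone does not mark proximal tubule nuclei. Proximal tubule nuclei may still be among those left out of the main comparison. Cluster 27, with 46 Sham nuclei, had the lipid droplet genes Plin1 at 1171 CPM and Cidec at 962 CPM, which are fat cell genes. These genes were chosen after their values were seen.

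A follow-up with several mice per group, a stated time after the procedure and matched hours of collection would show which of these differences recur. Staining for Havcr1, Krt20 and Lcn2 on sections would place the RNA in its cells without free RNA.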
